A study of Mus musculus with 20 samples.

How the data were processed

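Serum RNA of 20 samples from female mice was analysed, 5 from each of 4 groups set by genotype (normal or Ames dwarf) and age (5 to 6 or 21 to 22 months). RNA was extracted with a column kit and libraries were made with a TruSeq small RNA kit, per the submitters. Bowtie 0.12.8, bedtools, edgeR and the GRCm38 (mm10) genome are named in the submitters' processing notes, without a statement of what each was used for. The deposited table has the layout of the miRDeep2 quantifier, per the file headers, with a row for each pair of mature miRNA and precursor.

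The deposited values used for all tests were whole-number read counts, 1 column per sample, per the file headers. A second column per sample held RPM values made by the authors, which are reads scaled to a common library size, and each deposited RPM value matched the count divided by its column sum to within 0.005 RPM. RPM values were not used in any test, since the column sums count a read again in each precursor row it matches. No sample column was left unused (0 columns). A second file was the authors' deposited miRDeep2 report on all samples together, which holds hairpin candidates with a score and read numbers and has no values per sample. Fragments of tRNA, which the series also concerns, were not analysed here.

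The count table held 2241 rows for 1915 mature names, and 115 names had several rows. A read that matches several precursors is listed in each of their rows, so the row with the highest total over all samples was used for each name. At least 1 read was found for 1191 names. Among names with at least 10 reads, 36 fell into 17 sets with the same count in every sample (difference of 0), such as miR-486a-5p with miR-486b-5p, and their reads are shared. Total counts per sample ran from 1343137 to 4710263 with 1 row per name, and from 2174055 to 8014916 over all rows. No pair of samples had identical columns.

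Counts were tested with the quasi-likelihood test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3) in a model with a coefficient for each of the 4 groups. All 20 samples shared the estimate of spread. Library sizes were scaled with TMM factors, and low miRNAs were removed with the default filter of edgeR by group (minimum count 10), which left 360 miRNAs and at least 99.9% of reads in each sample. The common biological coefficient of variation was 47.5%. Benjamini-Hochberg adjustment ran over the 360 miRNAs within each comparison, and an adjusted p under 0.05 is called changed. Log2 fold changes are given with a standard error, computed as the size of the fold change over the square root of the F statistic. Levels are CPM, scaled to TMM-adjusted library size, as mean ± SD over 5 samples. The comparisons were dwarf against normal at each age, old against young in each genotype, and the difference of the age effects between genotypes. Standard errors cover the spread between samples, and amplified reads are not independent molecules. Intervals of list medians, given in brackets further below, come from resampling the members of a list. They leave out the spread between samples and treat members that move together as independent. The intervals of miR-34c-5p were built from its standard error.

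Before the data were examined, 16 miRNA lists were fixed: liver, erythroid, myeloid and platelet, lymphocyte, endothelial, muscle, neural and endocrine, epithelial, let-7, miR-34 and miR-449, miR-17~92 with its paralogs, miR-29, miR-30, inflammation, the imprinted Dlk1-Dio3 locus and the Sfmbt2 cluster. The 15 lists with at least 3 tested members were tested with camera (preset correlation 0.01), again with an estimated correlation, and with fry. Benjamini-Hochberg adjustment ran over the lists within a comparison. Some miRNAs stand on more than 1 list. The same plan fixed the tests, the alternatives and the rule for naming miRNAs. That rule took up to 10 higher and 10 lower called miRNAs by smallest p with a mean of at least 10 CPM in a group compared, the 5 smallest p where fewer than 5 were called, up to 4 members of each list by smallest p, and miR-451a, miR-23a-3p, miR-16-5p, miR-486a-5p and miR-122-5p in every comparison. A miRNA named in 1 comparison could be followed through the others, and names outside the rule are said to have been chosen after their values were seen.

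The haemolysis index was the log2 ratio of miR-451a to miR-23a-3p counts, each plus 1. The index, total counts and the number of miRNAs detected after thinning each sample to 1343137 reads were compared with 2-sided exact permutation tests of 5 against 5 samples, adjusted over the 4 pairwise comparisons. Fold changes of the comparisons that share the old normal libraries were set beside 20 simulated data sets with no effect and each miRNA drawn independently. They were also set beside fits, added after the values were seen, in which the old normal libraries were split between these comparisons. Positions come from GENCODE M21 on GRCm38, matched on the precursor gene's symbol, for 341 of the 360 miRNAs. Where old normal libraries held no read of a miRNA, its fold was bounded against 3 reads over the group.

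The edgeR step was tested on simulated counts drawn with the real means and library sizes. Many miRNAs were changed at once and each was drawn independently, so structure shared between miRNAs was left out. The shares recovered therefore need not hold in the real comparisons. Of the tested miRNAs changed 4-fold, 89.5% were recovered in old dwarf against old normal, 83.3% in old against young normal, 85.7% in young dwarf against young normal and 95.0% in old against young dwarf. For the difference of age effects the share was 46.2%. At 2-fold the shares were 33.3%, 30.4%, 21.4%, 13.6% and 0%, in the same order.

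Alternatives covered RLE size factors, library totals and upper-quartile factors in place of TMM, DESeq2 1.42.0, no low-count filter, a filter of at least 50 reads in at least 5 samples, fits on the 2 groups compared, the haemolysis index as a covariate, the replicate number as a block, the sum or mean of precursor rows, robust dispersion, removal of the 2 most abundant miRNAs, and leaving out each sample in turn. Covariates of the lymphocyte and the erythroid list mean, and counting names with identical counts once, were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables, exact tests and figures.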

Results

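Ames dwarf mice are small and outlive their normal siblings. The series asks whether miRNAs in serum change with age differently in these mice. Serum small RNA of female normal and Ames dwarf mice was compared at 5 to 6 months (young) and 21 to 22 months (old), with 5 libraries per group. The labels do not say whether the samples come from separate mice, so the p-values below measure the spread between these samples. Libraries held 1343137 to 4710263 miRNA counts, 2808131 ± 1286067 in young normal, 2660654 ± 1010545 in old normal, 2084127 ± 236567 in young dwarf and 2185682 ± 918958 in old dwarf mice (mean ± SD). The groups were not separated by total counts (smallest adjusted p 0.841, exact permutation tests) or by the number of miRNAs detected at equal depth, 583.2, 556.6, 604.4 and 565.4 in the same order (adjusted p 0.222 or higher, exact). Of 1191 miRNAs with a read, 360 were tested.

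A few miRNAs made up most of the serum reads. The red-cell miRNA miR-486a-5p shares its reads with miR-486b-5p. With names of identical counts counted once, which lowers the totals above, it alone took 35.8 ± 7.08% of counts in young normal, 44.4 ± 3.44% in old normal, 30.6 ± 6.94% in young dwarf and 39.97 ± 6.29% in old dwarf mice. The red-cell miRNA miR-451a reached 36605 ± 13087, 18409 ± 5950, 32903 ± 8664 and 30615 ± 6767 CPM (counts scaled to library size) in the same order. Its gene lies on chromosome 11 at 78073170 to 78073241 (GRCm38, GENCODE M21), between genes. The haemolysis index, the log2 ratio of miR-451a to miR-23a-3p, was 5.45 ± 0.61 in young normal, 4.30 ± 0.70 in old normal, 5.40 ± 0.43 in young dwarf and 5.38 ± 0.44 in old dwarf mice. It was 1.08 higher in old dwarf than in old normal mice (exact p 0.00794, adjusted p 0.0317), and fell by 1.15 with age in normal mice (exact p 0.0238, adjusted p 0.0476). The genotype difference was 0.78 without old normal replicate 2 and 1.05 without old normal replicate 4 (exact, adjusted p 0.0635 for both). The age difference had an adjusted p over 0.05 in the exact test without young normal replicates 2 (-1.21, adjusted p 0.0635), 3 (-0.94, 0.0952), 4 (-1.08, 0.0952) or 5 (-1.16, 0.0952), or old normal replicates 2 (-0.85, 0.0794), 4 (-1.12, 0.0635) or 5 (-1.23, 0.0635). Old normal replicate 2 had the lowest index, 3.13, against 4.20 to 4.83 in the other old normal libraries.

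**Figure D1:**
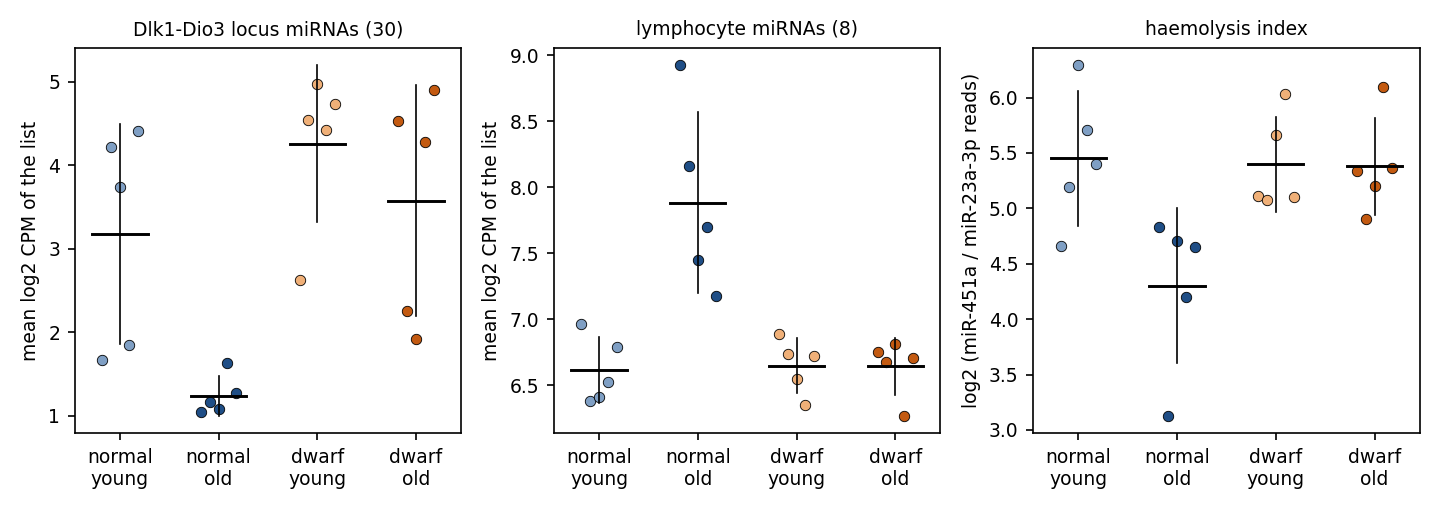
Mean log2 CPM of the Dlk1-Dio3 and lymphocyte lists and the haemolysis index in each library. Bars show mean ± SD over 5 libraries per group.

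Young dwarf and young normal serum did not differ in any single miRNA past the threshold, but the liver miRNAs lay higher in dwarf serum. The median log2 fold change of the liver list was 1.37, with all 7 tested members higher (camera adjusted p 1.04e-05, 0.439 with an estimated correlation and 0.309 with fry), and 5 were higher when adjusted over the list alone. The median was log2 2.11 without young normal replicate 3 (adjusted p 4.75e-06) and 0.74 without young dwarf replicate 3 (0.000112). miR-802-5p stood at 66.4 ± 60.6 CPM in young dwarf and 11.4 ± 4.93 CPM in young normal mice (log2 2.54 ± 0.70 SE, edgeR adjusted p 0.183, n = 5). miR-192-5p stood at 12060.5 ± 6637 and 4651 ± 1465 CPM (log2 1.37 ± 0.40, adjusted p 0.206). miR-148a-3p was higher by log2 0.67 and the hepatocyte miRNA miR-122-5p by log2 1.63 ± 1.18 (adjusted p 0.446 and 0.6998). Without young dwarf replicate 3 these were log2 0.43 and 0.53 (0.897 and 0.984), and miR-122-5p was log2 2.87 without young normal replicate 3 (0.534). In the liver list mean, young dwarf replicates 3 and 5 and old dwarf replicates 4 and 5 stood apart at 8.45, 7.79, 8.58 and 7.81 log2 CPM, against 5.44 to 6.63 in the other 16 libraries. Mir802 lies on chromosome 16 at 93369720 to 93369816 and Mir192 on chromosome 19 at 6264844 to 6264932, both between genes.

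Of the 5 smallest p-values in young mice, 3 belonged to miRNAs lower in dwarf serum, none past the threshold. miR-335-3p, from an intron of the imprinted gene Mest (chromosome 6, 30741299 to 30741396), stood at 5.93 ± 1.78 CPM against 20.7 ± 16.1 CPM in normal mice (log2 -1.79 ± 0.45, edgeR adjusted p 0.183). miR-205-5p, a miRNA of epithelia encoded in 4631405K08Rik (chromosome 1, 193507463 to 193507530), stood at 94.1 ± 49.2 against 263.5 ± 115.9 CPM (log2 -1.48 ± 0.39), and miR-5113 at 5.00 ± 2.19 against 13.6 ± 6.33 CPM (log2 -1.45 ± 0.41), both with an adjusted p of 0.183. The epithelial list held 1 member higher and 1 lower when adjusted over the list alone, with a median of log2 -0.09 that was 0.20 without young normal replicate 2. The Sfmbt2 cluster had a median of log2 -1.02 with all 4 names lower (camera adjusted p 0.00369, 0.571 with an estimated correlation, 0.309 with fry, and 0.0525 with summed precursor rows). Its 4 names hold only 2 separate counts, fewer than the 3 needed for a list, because they share reads in pairs, such as miR-669a-3p with miR-669o-3p (log2 -1.32, adjusted p 0.446). The Dlk1-Dio3 miRNAs all lay higher in dwarf serum, 30 of 30, with a median of log2 0.93 (camera adjusted p 3.04e-10, 0.571 with an estimated correlation and 0.580 with fry), yet 0 passed when adjusted over the list alone. Dlk1-Dio3 miR-434-3p stood at 468.9 ± 179 against 194 ± 124.1 CPM (log2 1.27 ± 0.50, adjusted p 0.407).

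The erythroid list had a median of log2 -0.31 (camera adjusted p 0.0635) and passed without young normal replicates 2 (0.0112) or 5 (0.0148) or young dwarf replicates 1 (log2 -0.57, 0.0327) or 4 (0.0183), while it was log2 -0.17 without young normal replicate 4 (0.560). The muscle list, with a median of log2 0.33, passed only without young normal replicate 2 (log2 0.70, adjusted p 0.0232, against 0.243), and its leave-one-out medians reached down to log2 0.07 without young normal replicate 1. All other lists had a camera adjusted p of 0.299 or higher. Endothelial miR-126a-5p and miR-126a-3p moved by log2 0.49 and 0.40 (edgeR adjusted p 0.460 and 0.641). In edgeR 28 miRNAs had a raw p under 0.05 and 0 passed adjustment, and DESeq2 called 3 higher and 3 lower. In simulated counts, 85.7% of the tested 4-fold changes and 21.4% of the 2-fold changes were recovered in this comparison. That simulation gave 48 calls and drew each miRNA independently, so these shares need not hold where 0 miRNAs pass.

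Old dwarf serum held more of 4 of 5 miR-34 and miR-449 miRNAs and 25 of 30 listed miRNAs of the imprinted Dlk1-Dio3 locus than old normal serum, and less of 6 of 8 lymphocyte miRNAs. As lists these passed with the preset correlation but not with an estimated correlation (camera adjusted p 0.299 for each). miR-34c-5p, a p53-responsive miRNA that restrains the cell cycle, stood at 77.0 ± 48.1 CPM in old dwarf and 3.63 ± 2.37 CPM in old normal mice (log2 4.45 ± 0.78, edgeR adjusted p 0.00304, n = 5). Dlk1-Dio3 miR-127-3p stood at 709.6 ± 577.7 against 26.9 ± 10.7 CPM (log2 4.72 ± 0.95, adjusted p 0.00304). Lymphocyte miR-150-5p stood at 935.5 ± 315.3 against 2904 ± 1561 CPM (log2 -1.63 ± 0.38, adjusted p 0.00601). In all, 58 miRNAs were higher and 37 lower in old dwarf serum.

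Of the 5 tested members of the miR-34 and miR-449 list, 4 rose in old dwarf against old normal mice, and the same 4 when adjusted over the list alone (median log2 2.71, camera adjusted p 0.00168, 0.299 with an estimated correlation). miR-34b-3p and miR-34c-3p were higher by log2 2.71 ± 0.55 and 2.74 ± 0.61 (adjusted p 0.00304 and 0.00547). miR-449a-5p, which shares the seed of miR-34c-5p, stood at 4.12 ± 1.08 against 0.714 ± 0.665 CPM (log2 2.27 ± 0.59, adjusted p 0.0113). miR-34a-5p, encoded elsewhere, was not past the threshold (log2 1.06, adjusted p 0.250, and log2 0.65 without old dwarf replicate 5, 0.564). Mir34c and Mir34b lie side by side on chromosome 9 (51103034 to 51103110 and 51103562 to 51103645), opposite an intron of Btg4, and Mir449a lies in an intron of Cdc20b (chromosome 13, 113037534 to 113037624). miR-592-5p also stood higher, at 43.0 ± 72.8 against 3.17 ± 1.99 CPM (log2 3.69 ± 0.85, adjusted p 0.00581), with old dwarf replicate 1 at 172 CPM, replicate 2 at 26.9 CPM and replicates 3 to 5 at 4.97 to 5.63 CPM. Without old dwarf replicate 1 the difference of miR-592-5p was log2 1.72 (adjusted p 0.0442).

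Of the 30 tested names on the Dlk1-Dio3 list, 25 rose in old dwarf against old normal serum and all 30 when adjusted over the list alone. The list median was log2 3.69, or 3.60 with miR-369-5p at its bound, since old normal libraries held no read of that miRNA (camera adjusted p 1.88e-15, 0.299 with an estimated correlation). Of these names, miR-299a-3p and miR-299b-3p share all reads. The listed members lie on chromosome 12 between 109585789 and 109743795, and the miRNAs of the locus are expressed from the maternal chromosome. miR-673-5p, encoded shortly before this stretch (109571990 to 109572080), is not on the list and was chosen after its values were seen. It was higher by log2 2.70 ± 0.93 (adjusted p 0.0401, and over 0.05 in 8 of 20 fits with 1 library left out, highest 0.0982). miR-136-5p had the largest named difference, 62.6 ± 54.7 against 1.18 ± 0.794 CPM (log2 5.59 ± 1.10). miR-411-5p, miR-541-5p, miR-434-5p, miR-431-5p, miR-410-3p and miR-434-3p were higher by log2 4.91, 4.63, 4.40, 3.76, 3.45 and 2.84 (adjusted p 0.00304 for each). Mir431, Mir127, Mir434 and Mir136 lie opposite an exon of Rtl1 between 109590447 and 109595388, while Mir541, Mir409 and Mir410 lie within Mirg between 109742409 and 109743795. In the list mean, old normal libraries held 1.05 to 1.64 log2 CPM, and old dwarf replicates 1 to 5 held 4.53, 2.26, 1.92, 4.29 and 4.90 log2 CPM. Over the 20 libraries this mean went with those of the muscle list (r 0.859, and 0.768 within groups) and the miR-30 family (0.742 and 0.514). It went against those of the neural and endocrine (-0.904 and -0.847), myeloid and platelet (-0.862 and -0.746), Sfmbt2 (-0.787 and -0.529) and erythroid lists (-0.770 and -0.865).

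**Figure D2:**
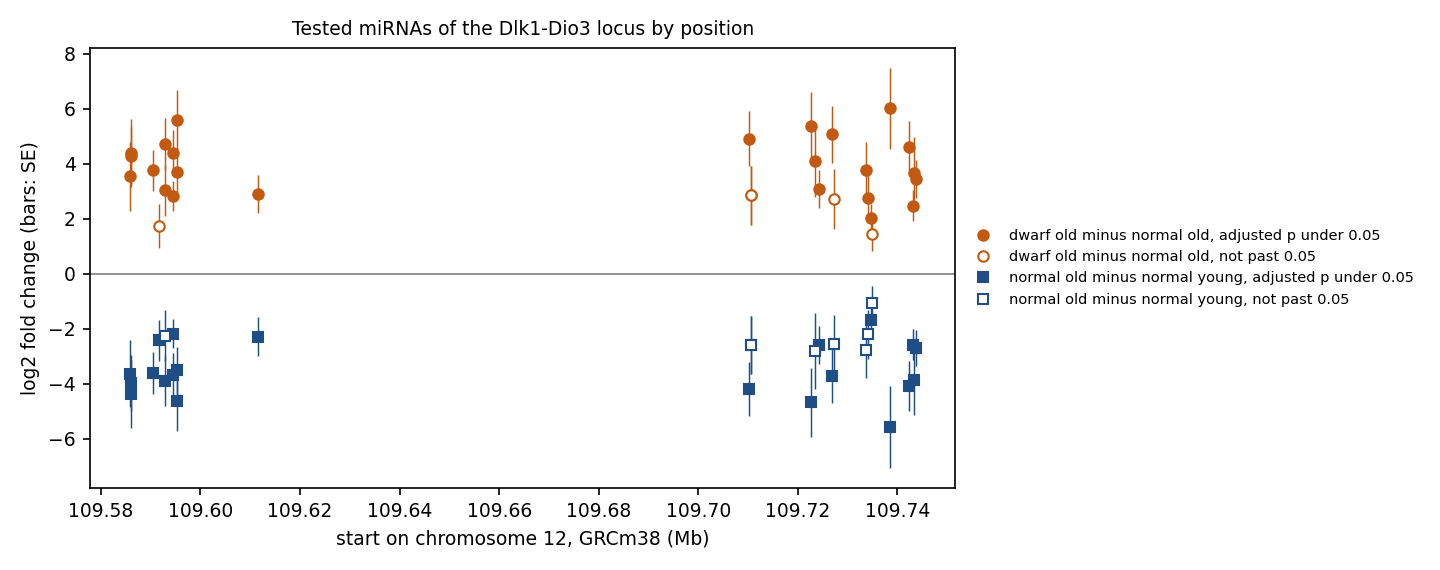
Log2 fold change ± SE of the Dlk1-Dio3 miRNAs by position on chromosome 12, for old dwarf against old normal mice and old against young normal mice. Filled symbols have an adjusted p under 0.05, and miR-369-5p is left out.

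Of the 8 lymphocyte miRNAs, 6 fell in old dwarf against old normal serum, and 7 when adjusted over the list alone (median log2 -1.42, camera adjusted p 0.00174, 0.299 with an estimated correlation). Without old normal replicate 1 the median was log2 -0.93 (adjusted p 0.00471). miR-342-3p, from an intron of Evl (chromosome 12, 108658620 to 108658718), stood at 53.9 ± 17.8 against 151.2 ± 68.7 CPM (log2 -1.49 ± 0.32, adjusted p 0.00479). miR-150-3p was lower by log2 -3.04 ± 0.74 (adjusted p 0.0076). miR-146a-5p was lower by log2 -2.27 (adjusted p 0.0103), and without old normal replicate 1, which held 1896 CPM, by log2 -0.82 (adjusted p 0.0563). miR-155-5p was lower by log2 -1.35 (adjusted p 0.0196), and without the same library by log2 -0.78 (adjusted p 0.0988). miR-5107-5p, from an exon of Cd74, the invariant chain of antigen presentation (chromosome 18, 60812076 to 60812163), was lower by log2 -3.05 ± 0.72 (adjusted p 0.00683), and without old normal replicate 1 by log2 -1.995 (0.034). miR-1249-3p and miR-501-3p were lower by log2 -1.37 and -1.09 (adjusted p 0.0113 for both), the latter not past the threshold with library totals (0.0571) or no filter (0.0597). miR-669a-5p of the Sfmbt2 cluster, whose reads are shared with miR-669p-5p, stood at 12.3 ± 5.95 against 44.0 ± 10.6 CPM (log2 -1.82 ± 0.39, adjusted p 0.00381). That cluster had a median of log2 -1.58, with 2 of 4 names past the threshold and 4 when adjusted over the list alone (camera adjusted p 0.0039, 0.337 with an estimated correlation), again from 2 separate counts.

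In old dwarf against old normal mice 3 of 8 miRNAs of the miR-30 family rose, and 4 when adjusted over the list alone, among them miR-30a-3p at 304.5 against 130 ± 24.3 CPM (log2 1.23 ± 0.32, adjusted p 0.0113), while the list was not past the threshold with camera (adjusted p 0.226) but was with fry (0.00789). The muscle list had a median of log2 1.53 with all 8 members higher and 0 called. Its camera adjusted p of 0.0421 (0.526 with an estimated correlation, 0.0735 with fry, 0.0587 with identical names counted once) did not hold with each library left out, and was 0.0713 without old normal replicate 1, 0.118 without old normal replicate 5, and 0.0857, 0.0571, 0.0612 and 0.0626 without old dwarf replicates 2, 3, 4 and 5, while the median was log2 2.48 without old normal replicate 4 (0.00235). Of the myeloid and platelet miRNAs 3 of 9 fell, and 3 when adjusted over the list alone (median log2 -0.59, camera adjusted p 0.0407, 0.459 with an estimated correlation). That list had an adjusted p of 0.0592 and 0.0764 without old normal replicates 4 and 5, and 0.0623 and 0.0612 without old dwarf replicates 3 and 4. The inflammation list held 1 member higher and 3 lower, and 2 higher and 5 lower when adjusted over the list alone (camera adjusted p 0.313, and 0.0253 with fry). The liver list had a median of log2 0.98 with all 7 higher (camera adjusted p 0.226). It was log2 1.57 without old dwarf replicate 1 (0.049999) or 2 (0.147), 1.56 without old dwarf replicate 3 (0.141), 1.50005 without old normal replicate 3 (0.118) and 0.29 without old dwarf replicate 4 (0.493). The let-7 family had a median of log2 0.28 with all 9 higher (0.230), and of log2 0.12 without old normal replicate 1, 0.18 without old dwarf replicate 1 and 0.44 without old normal replicate 5. The neural and endocrine, epithelial and miR-17~92 lists had medians of log2 -0.59, -0.93 and -0.19, and miR-29 a median of log2 0.00 with a mean of -0.06. The epithelial median was log2 0.40 without old normal replicate 1 (0.698), so its sign rested on that library, and the miR-17~92 median was -0.02 without it and -0.30 without old normal replicate 2. The neural and endocrine list passed with fry (adjusted p 0.0476) but not with camera (0.226). The erythroid list had a median of log2 -0.32, -0.06 with identical names counted once, and -0.21 and -0.51 without old dwarf replicates 1 and 3, unlike miR-451a, which was log2 0.73 ± 0.28 higher (adjusted p 0.055, and 0.0365 and 0.0395 without old dwarf replicates 2 and 3, 0.0399 and 0.0439 without young normal replicates 1 and 3).

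In old dwarf against old normal mice, the count of 95 came to 53, 143, 55 and 51 without old dwarf replicates 1, 2, 4 and 5. With the haemolysis index in the model, which itself differed between these groups by 1.08 (exact p 0.00794), 0 miRNAs passed in edgeR, and DESeq2 called 136 without it. The raw p was under 0.05 for 163 miRNAs. Library totals without TMM factors shifted the median of all miRNAs to log2 0.23 and upper-quartile factors to -0.11, against -0.06.

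Old normal serum held less of 22 of 30 Dlk1-Dio3 miRNAs and more of 6 of 8 lymphocyte miRNAs than young normal serum. As lists these did not pass with an estimated correlation (camera adjusted p 0.459 and 0.344). Dlk1-Dio3 miR-127-3p fell with age from 403.5 ± 370.1 to 26.9 ± 10.7 CPM (log2 -3.90 ± 0.92, edgeR adjusted p 0.0115, n = 5). Lymphocyte miR-342-3p rose from 41.4 ± 9.58 to 151.2 ± 68.7 CPM (log2 1.87 ± 0.33, adjusted p 0.00527). In all, 18 miRNAs rose and 38 fell with age in normal mice.

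Of the 30 listed Dlk1-Dio3 names, 22 fell with age in normal mice, and 28 when adjusted over the list alone. The median was log2 -3.16, or -2.98 with miR-369-5p at its bound (camera adjusted p 1.87e-14, 0.459 with an estimated correlation). miR-136-5p, miR-411-5p, miR-541-5p, miR-434-5p, miR-431-5p, miR-136-3p, miR-409-3p and miR-434-3p fell by log2 4.63, 4.17, 4.07, 3.68, 3.60, 3.51, 2.57 and 2.18 (adjusted p 0.0115 for each). miR-673-5p, not on the list, differed by log2 -2.52 ± 0.92 (adjusted p 0.0644), and passed without young normal replicates 1 (0.0299) or 4 (0.0221) or old normal replicate 5 (0.0373). The list means of young normal replicates 1 to 5 were 1.66, 4.22, 3.75, 1.85 and 4.41 log2 CPM, so replicates 1 and 4 lay close to the old normal libraries.

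Of the 8 lymphocyte miRNAs, 6 rose with age in normal mice, and 6 when adjusted over the list alone (median log2 1.60, camera adjusted p 0.000223, 0.344 with an estimated correlation). miR-150-5p rose from 1061 ± 479.5 to 2904 ± 1561 CPM (log2 1.45 ± 0.38, adjusted p 0.0161), and its gene lies on chromosome 7 at 45121757 to 45121821. miR-150-3p, miR-155-5p and miR-146a-5p rose by log2 2.87, 1.75 and 2.65 (adjusted p 0.0126, 0.0115 and 0.0115), and miR-146a-5p by log2 1.19 without old normal replicate 1 (0.0383). In a fit of these groups alone, miR-150-5p had an adjusted p of 0.0559, miR-155-5p 0.061, miR-146a-5p 0.0514 and miR-501-3p 0.0747. The lymphocyte list mean was 7.18 to 8.93 log2 CPM in old normal libraries and 6.27 to 6.96 in all others. miR-5107-5p, encoded in Cd74, rose by log2 3.48 ± 0.73, and miR-671-3p and miR-501-3p by log2 1.44 and 1.18 (adjusted p 0.0115 for each, and for miR-501-3p 0.0838 with library totals and 0.0643 with no filter). Of the inflammation list, which shares members with the lymphocyte list, 4 of 10 rose, and 4 rose and 1 fell when adjusted over the list alone (camera adjusted p 0.162, and 0.0144 with fry).

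Among other miRNAs, miR-195a-5p of the growth-restraining miR-15 family fell with age in normal mice from 74.9 ± 40.7 to 20.5 ± 4.85 CPM (log2 -1.86 ± 0.45, adjusted p 0.0115). Of the let-7 family 2 of 9 fell, and 3 when adjusted over the list alone, with a median of log2 -0.45 (camera adjusted p 0.0121, 0.513 with an estimated correlation, 0.0515 without young normal replicate 1 and 0.0507 without old normal replicate 1). let-7d-5p fell from 472.4 ± 90.5 to 281.9 ± 58.7 CPM (log2 -0.74 ± 0.18, adjusted p 0.0125). Of the miR-34 and miR-449 list 2 of 5 fell, and 2 when adjusted over the list alone (median log2 -1.20, camera adjusted p 0.0674, 0.0268 with fry, and 0.0414 without young normal replicate 4). miR-449a-5p fell by log2 2.03 ± 0.59 (adjusted p 0.0233, and 0.0631 and 0.0559 without young normal replicates 3 and 5). miR-34c-5p fell from 18.2 ± 12.6 to 3.63 ± 2.37 CPM (log2 -2.38 ± 0.74, adjusted p 0.0323), with adjusted p 0.0955 and 0.0846 without young normal replicates 3 and 5 and 0.0784, 0.0758 and 0.053 without old normal replicates 1, 3 and 4. miR-451a fell by log2 0.99 ± 0.28 (adjusted p 0.0198, and 0.0747 without young normal replicate 3), while miR-16-5p, miR-23a-3p, miR-486a-5p and miR-122-5p were not past the threshold.

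The muscle list had a median of log2 -1.49 in old against young normal mice (camera adjusted p 0.0637), and passed without young normal replicates 1 (0.0293), 3 (0.0403) or 4 (0.0414) or old normal replicate 4 (log2 -2.51, adjusted p 0.00355). The Sfmbt2 cluster had a median of log2 0.81 with 2 higher when adjusted over the list alone (camera adjusted p 0.0835, 0.0414 without young normal replicate 4 and 0.0359 without old normal replicate 1). The liver, erythroid, myeloid and platelet, neural and endocrine and epithelial lists had medians of log2 0.08, -0.05, 0.41, 0.56 and 0.69, and miR-30, miR-29 and miR-17~92 of -0.33, -0.07 and -0.03, none past the threshold. The epithelial median was log2 -0.53 without old normal replicate 1 (0.229) and 1.04 without young normal replicate 2 (0.554). The liver, erythroid, miR-29 and miR-17~92 medians, close to 0, changed sign with single libraries left out, and the liver median was log2 0.65 without young normal replicate 3. The means of the erythroid, miR-29 and miR-17~92 lists had the other sign, log2 0.02, 0.03 and 0.09. The count of 56 came to 123, 37 and 29 without young normal replicates 1, 3 and 5 and to 37 without old normal replicate 1. With the haemolysis index, itself 1.15 lower in old normal mice (exact p 0.0238), in the model 1 miRNA passed. DESeq2 called 39 higher and 78 lower. Library totals gave 9 higher and 97 lower and moved the median of all miRNAs to log2 -0.42, and upper-quartile factors gave 33 and 36 with a median of 0.16, against 0.00.

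Old and young dwarf serum differed in 2 miRNAs, both higher in old mice. miR-592-5p, encoded in an exon of the glutamate receptor gene Grm8 (chromosome 6, 27936655 to 27936750), rose with age from 1.90 ± 1.05 to 43.0 ± 72.8 CPM (log2 4.49 ± 0.89, edgeR adjusted p 0.0232, n = 5). miR-34c-3p rose from 1.62 ± 0.365 to 11.1 ± 10.4 CPM (log2 2.73 ± 0.59, adjusted p 0.0292). The miR-34 and miR-449 list rose as a set, with a median of log2 1.66, 1 of 5 called and 3 when adjusted over the list alone (camera adjusted p 2.76e-07, and 0.0128 with an estimated correlation). miR-34c-5p was higher by log2 2.03 ± 0.67 (18.7 ± 15.4 to 77.0 ± 48.1 CPM) and miR-34b-3p by log2 1.66 ± 0.50, neither past the threshold (adjusted p 0.470 and 0.309). miR-34a-5p was higher by log2 1.05 (adjusted p 0.997, and log2 0.65 without old dwarf replicate 5, 0.964), and miR-449a-5p differed by log2 0.12. miR-592-5p lost its call without young dwarf replicates 1 (log2 4.59, adjusted p 0.0739), 2 (4.30, 0.115), 3 (4.34, 0.099), 4 (4.44, 0.0839) or 5 (4.84, 0.0523), or old dwarf replicate 1 (2.51, 0.0786). miR-34c-3p lost its call without young dwarf replicates 1 (log2 2.79, adjusted p 0.0739), 2 (2.66, 0.158), 3 (2.80, 0.099), 4 (2.80, 0.0839) or 5 (2.63, 0.129), or old dwarf replicates 1 (2.67, 0.0786), 3 (2.02, 0.208) or 4 (2.83, 0.0522).

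**Figure D3:**
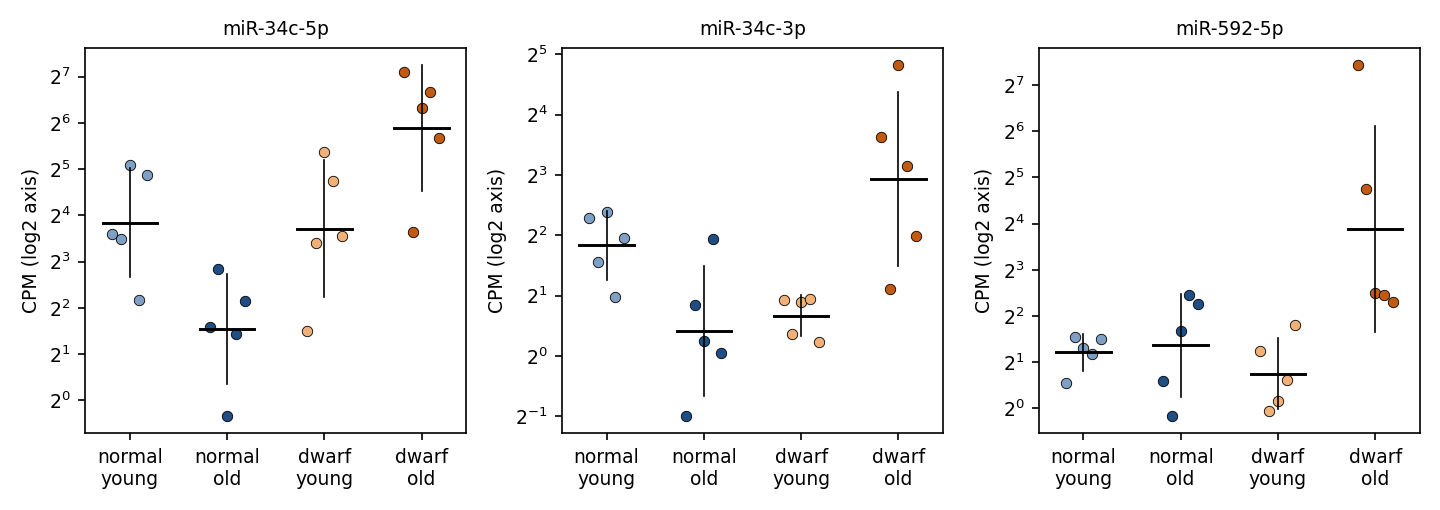
CPM of miR-34c-5p, miR-34c-3p and miR-592-5p in each library on a log2 axis. Bars show mean ± SD of log2 values.

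Of the lymphocyte and Dlk1-Dio3 lists, 6 of 8 and 22 of 30 members were called with age in normal mice (camera adjusted p 0.344 and 0.459 for the lists with an estimated correlation), and none with age in dwarf mice. miR-127-3p stood at 780.1 ± 371.4 CPM in young and 709.6 ± 577.7 CPM in old dwarf mice, miR-150-5p at 963.9 ± 339.8 and 935.5 ± 315.3 CPM, and miR-342-3p at 47.2 ± 10.9 and 53.9 ± 17.8 CPM. The Dlk1-Dio3 median was log2 -0.44 with all 30 lower and none called (camera adjusted p 1.38e-06, 0.792 with an estimated correlation, 0.816 with fry), and log2 -0.17 without old dwarf replicate 2 (adjusted p 0.154). It was log2 -0.29 without old dwarf replicate 3 (0.0389), and -0.71, -0.67 and -0.84 without young dwarf replicate 1 and old dwarf replicates 4 and 5. The erythroid list had a median of log2 0.19 (adjusted p 0.0773) and passed without young dwarf replicates 1 (0.0191) or 4 (0.0128) or old dwarf replicates 1 (0.0185) or 4 (0.0403), while its leave-one-out medians ran from log2 -0.04 without old dwarf replicate 3 to 0.39 without young dwarf replicate 1. The muscle list passed only without young dwarf replicate 1 (0.0225), and the miR-17~92 list only without young dwarf replicate 5 (0.0285) or old dwarf replicate 3 (0.0314), and the remaining lists were not past the threshold. miR-501-3p and miR-19a-3p moved by log2 0.96 ± 0.29 and -0.89 ± 0.31 (edgeR adjusted p 0.309 and 0.470). Here 14 miRNAs had a raw p under 0.05, DESeq2 called 2, and library totals moved the median of all miRNAs to log2 -0.38 and upper-quartile factors to 0.13, against 0.02. In this comparison the count of 2 became 0 without old dwarf replicate 1 or any of young dwarf replicates 1, 2, 3, 4 and 5, and 1 without old dwarf replicate 3 or 4.

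The change with age was called different between genotypes for both arms of miR-34c, close to the threshold. With 1 library left out, the call was lost in 17 of 20 fits for miR-34c-5p and in 16 for miR-34c-3p. Since 5 of 100 splits of the same libraries, the real one included, gave at least as many calls, chance stays open. For miR-34c-5p, the age effect in dwarf mice exceeded that in normal mice by log2 4.42 ± 0.998, and for miR-34c-3p by log2 3.93 ± 0.85 (edgeR adjusted p 0.0472 for both, n = 5 in each of 4 groups). miR-34c-5p went from 18.2 to 3.63 CPM in normal and from 18.7 to 77.0 CPM in dwarf mice. The miR-34 and miR-449 list had a median difference of log2 2.77, with 2 of 5 called and 4 when adjusted over the list alone (camera adjusted p 2.64e-06, and 0.0369 with an estimated correlation). miR-34b-3p differed by log2 2.77 ± 0.74 (adjusted p 0.131, and 0.0466 without old dwarf replicate 2). miR-592-5p differed by log2 4.04 ± 1.24 and miR-449a-5p by log2 2.15 ± 0.77, not past the threshold (adjusted p 0.134 and 0.181). Without old dwarf replicate 1 the miR-592-5p difference was log2 2.07 (0.299).

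The Dlk1-Dio3 miRNAs had a median difference of log2 2.70 between the age effects, with 0 called and 17 higher when adjusted over the list alone (camera adjusted p 1.24e-10, 0.490 with an estimated correlation, 0.215 with fry). miR-136-5p, miR-541-5p, miR-434-5p and miR-431-5p differed by log2 4.37, 3.85, 3.39 and 3.30 (edgeR adjusted p 0.134 for each). The lymphocyte miRNAs had a median of log2 -1.59, with 0 called and 5 lower when adjusted over the list alone (camera adjusted p 3.15e-05, 0.109 with an estimated correlation), and a median of log2 -0.99 without old normal replicate 1 (0.000174). miR-342-3p differed by log2 -1.68 ± 0.45 and miR-150-3p by log2 -3.10 ± 1.03 (adjusted p 0.131 and 0.175). The let-7 family had a median of log2 0.42 (camera adjusted p 0.0427, 0.543 with an estimated correlation, 0.186 with fry), and lost its call without young normal replicates 1 (0.0934), 3 (0.0619) or 4 (0.103), old normal replicates 1 (0.134), 2 (0.0729) or 3 (0.0518), young dwarf replicates 2 (0.0522), 3 (0.171) or 5 (0.0848), or old dwarf replicates 1 (0.0835), 2 (0.104) or 3 (0.0762). The liver list had a median of log2 -0.39 (camera adjusted p 0.233), which ran from log2 -0.12 without old normal replicate 1 to -1.01 without old dwarf replicate 4 (0.0128). The myeloid and platelet list passed only without old normal replicate 1 (0.042) or old dwarf replicate 2 (0.0425), and the muscle list only without old normal replicate 4 (log2 2.05, 0.011, against 1.18), while its median was log2 0.71 without young normal replicate 2 (0.390).

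For the difference of age effects, 57 miRNAs had a raw p under 0.05, and DESeq2 called 17 higher and 3 lower, with miR-136-5p, miR-541-5p, miR-434-5p and miR-592-5p among the higher. With 1 library left out, the difference ran from log2 4.08 to 4.91 for miR-34c-5p and from log2 3.23 to 4.53 for miR-34c-3p. Both arms lost their edgeR call without young normal replicates 1 (adjusted p 0.0516 for both arms), 2 (0.0514), 3 (0.122) or 5 (0.104), old normal replicates 1 (0.112), 2 (0.0623), 3 (0.112) or 5 (0.0613), young dwarf replicates 1 (0.0558), 2 (0.1004), 4 (0.0622) or 5 (0.116), or old dwarf replicates 1 (0.115), 3 (0.0652) or 4 (0.0822). miR-34c-5p also lost it without old normal replicate 4 (0.0726) or old dwarf replicate 5 (0.0501), and miR-34c-3p without young dwarf replicate 3 (0.0725). The count of 2 came to 3 without old dwarf replicate 2, to 1 without old normal replicate 4, young dwarf replicate 3 or old dwarf replicate 5, and to 0 without young normal replicates 1, 2, 3 and 5, old normal replicates 1, 2, 3 and 5, young dwarf replicates 1, 2, 4 and 5, or old dwarf replicates 1, 3 and 4, each left out alone. In simulated counts, with each miRNA drawn independently, 46.2% of tested 4-fold differences of age effects were recovered.

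**Figure D4:**
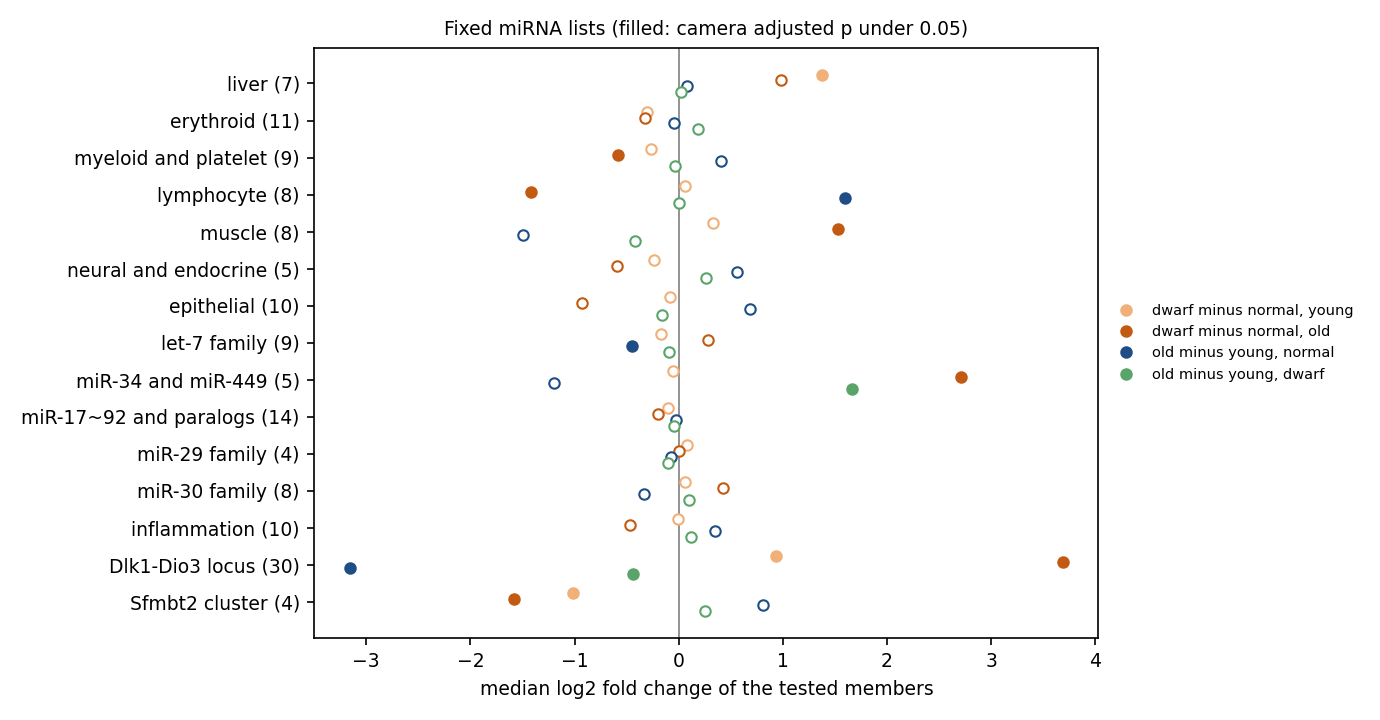
Median log2 fold change of each fixed list in the pairwise comparisons. Filled symbols have a camera adjusted p under 0.05.

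Across the 360 miRNAs, the genotype effects at both ages went the same way for 72.5% (Pearson r 0.607, Spearman rho 0.611), and the age effects in both genotypes for 67.8% (r 0.335, rho 0.477). Shared calls say nothing about similarity here, since young mice had 0 calls between genotypes and dwarf mice 2 with age (independent lists give 0.1 or fewer shared). The miRNAs lower in dwarf serum at both ages included miR-205-5p (log2 -1.48 in young mice, -1.20 in old mice) and miR-335-3p (log2 -1.79 and -1.64), with an adjusted p of 0.0299 and 0.0133 in old mice. miR-205-5p was not past the threshold in old mice without old normal replicates 2 (adjusted p 0.0738), 4 (0.0651) or 5 (0.0677) or old dwarf replicates 1 (0.0702), 4 (0.0885) or 5 (0.0902). Old dwarf against old normal and old against young normal share the old normal libraries. Their effects had opposite signs for 83.6% of miRNAs (r -0.915, covariance -1.88), against 67.0%, -0.513 and -0.119 in 20 simulated data sets with no effect. With the old normal libraries split between both comparisons, r was -0.79 (-0.828 to -0.767 over 20 splits) and the covariance -1.82 (-1.98 to -1.72). Of the miRNAs that fell with age in normal mice, 32 were higher in old dwarf than in old normal mice, where independent lists give 6.12, and of those that rose 13 were lower, where independent lists give 1.85. Simulated data sets with no effect gave 0 for both. Independent lists leave out the shared libraries and the simulation leaves out the effects, so part of the excess may come from the old normal libraries that both comparisons use. The simulation also drew each miRNA independently, although real miRNAs moved together, such as those of the Dlk1-Dio3 list (estimated correlation 0.84). Values beyond the simulated ones therefore do not exclude chance. With those libraries split, and so fewer in each comparison, the counts ran from 0 to 4 and from 0 to 3, with a median of 0 for both.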

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

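The comparison of single libraries for unlabelled serum handling, all tests with the erythroid list mean, the direction of the haemolysis index, the index in the model of miR-34c-5p, and the lymphocyte list set against other lists were chosen only after the result was seen, and the other tests in this part were planned before. In groups of 5 libraries, 18 of 220 groups had a library set apart from the rest by Dixon's criterion, where chance gives about 11 (about 1 in 20 groups). In the list means (log2 CPM, with the nearest other library of the group in brackets), the library set apart was old dwarf replicate 4 for lymphocyte, 6.27 (6.68), young dwarf replicate 1 for muscle, 4.67 (6.08), and for Dlk1-Dio3, 2.62 (4.43), and old normal replicate 1 for the Sfmbt2 cluster, 3.36 (4.24). In log2(CPM + 1), young dwarf replicate 1 was low for miR-127-3p, 7.24 (9.66), miR-136-3p, 5.55 (7.97), miR-136-5p, 3.32 (6.03), miR-409-3p, 3.39 (4.69), miR-410-3p, 5.14 (6.95), miR-411-5p, 4.35 (6.31), miR-434-5p, 3.68 (5.96) and miR-541-5p, 5.12 (7.72). These are all Dlk1-Dio3 miRNAs, so they are not 8 separate events. Old normal replicate 1 was high for miR-146a-5p, 10.89 (8.06), and low for miR-802-5p, 3.09 (4.46). Old normal replicate 2 was low for miR-451a, 13.04 (14.12), young dwarf replicate 3 high for miR-146a-5p, 7.32 (6.24), and low for miR-5113, 1.31 (2.54), and old dwarf replicate 3 high for miR-205-5p, 6.83 (6.12).

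The effect of age differed between genotypes, by a test of the difference itself, for miR-34c-3p (log2 3.93, dwarf minus normal) and miR-34c-5p (4.42), and, with camera, for the medians of the miR-34 and miR-449 list (2.77), the Dlk1-Dio3 list (2.70), the lymphocyte list (-1.59) and the let-7 list (0.42). With an estimated correlation the camera adjusted p was 0.0369 for the miR-34 and miR-449 list, and 0.490, 0.109 and 0.543 for the other lists in the same order, not past the threshold. With fry the Dlk1-Dio3 and let-7 lists were not past it either (adjusted p 0.215 and 0.186). With 1 library left out, the calls of miR-34c-5p, miR-34c-3p and the let-7 list were lost in 17, 16 and 12 of 20 fits. The call of miR-34c-5p was also lost in 8 of 12 settings chosen beforehand and that of miR-34c-3p in 5 of the 10 that tested it. In the authors' pooled miRDeep2 report, which enters no comparison, the highest-scoring hairpin candidate held 76420 reads, 76417 of them of its mature sequence. It lay on chromosome 14 (61543639 to 61543698, plus strand) and carried an alert for rRNA or tRNA sequence.

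Dlk1-Dio3 miRNAs were lower in old normal than in old dwarf serum. Dilution by blood-cell RNA of miRNAs from all solid tissues alike was argued against as the whole source. The Dlk1-Dio3 median exceeded the pooled median of the liver, muscle, neural and epithelial lists by log2 3.39 (2.60 to 4.20). That pool was mixed. The liver and muscle medians, log2 0.98 and 1.53, went the way dilution predicts, and the neural and epithelial medians, -0.59 and -0.93, the other way. Without old normal replicate 1 the epithelial median was log2 0.40. Normalization or a few abundant miRNAs was argued against, since the lowest median over the other settings was 3.72. For red-cell RNA, the planned test with the haemolysis index in the model did not decide. It also asked that enough called members stay called, and 0 of 25 did. Only a test chosen after the result was seen, the direction of the index, argued against red-cell RNA as the whole source. More of it in old normal tubes would need a higher haemolysis index there, but the index was 1.08 higher in old dwarf serum (exact p 0.00794, adjusted p 0.0317). The erythroid list did not follow the index (r 0.0638 within groups), and its median of log2 -0.32, or -0.06 with identical names counted once, went the other way, not past the threshold. With the erythroid list mean in the model the Dlk1-Dio3 median was 2.59 (2.19 to 3.35) and 24 of 25 calls were kept, and 3.08 and 26 of 26 with identical names counted once. The erythroid list itself differed little between these groups (camera adjusted p 0.80), so a model with its mean could hardly remove the difference. The kept calls therefore decide nothing about red-cell RNA as the whole source. Part of the difference could still follow the blood-cell share, since within groups the Dlk1-Dio3 mean went against the erythroid (r -0.865) and myeloid and platelet (-0.746) lists and with the muscle list (0.768). The neural and endocrine list (-0.847) did not go with the muscle list as a dilution of all solid tissues would need. Only 5 of its 17 names in the count table were tested, and their source in serum was not, so this weighs little against dilution. With the index in the model the median was 2.999 (2.71 to 3.54) against 3.69, but 0 of 25 calls were kept as the median standard error rose from 0.977 to 1.25, so the index may account for part of the difference. Unlabelled handling could also contribute and cannot be told apart from the group: 0 of 15 other libraries lay in the old normal range, but the lowest, at 1.66, lay beside the highest old normal library, at 1.64. On principal component 1, young normal replicate 1 (-14.9) lay within the range of the old normal libraries (-18.9 to -11.9). That component follows the Dlk1-Dio3 mean (r 0.991), so it is no separate evidence. The difference in genotype and age that the design names stays open and was not tested apart from these.

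miR-34c-5p rose with age in dwarf relative to normal mice. The sample structure of the Dlk1-Dio3 miRNAs was argued against as its whole source, since the interaction was log2 3.71 (1.98 to 5.44; raw p 0.000342 in edgeR) with their mean in the model, against 4.42. More epithelial RNA in old dwarf serum, as the epithelial list measures it, was argued against too, since the epithelial median was -0.16 (-0.27 to 0.07). An epithelial source that this list does not follow was not tested. For red-cell RNA, the interaction was log2 3.72 (1.41 to 6.03, raw p 0.00465 in edgeR) with the haemolysis index in the model. With the index the call was not kept (adjusted p 0.419), as the fold fell and its standard error rose from 0.998 to 1.16. With the erythroid list mean in the model the interaction was 4.65 (2.87 to 6.44, edgeR adjusted p 0.0159). That list had no clear interaction itself (median log2 0.28, camera adjusted p 0.318), so its mean could hardly remove that of miR-34c-5p. Red-cell RNA as a source is therefore not decided. The index was 5.38 in old and 5.40 in young dwarf mice, and with it in the model miR-34c-3p kept its call with age in dwarf mice (log2 2.72, adjusted p 0.0442). An index so alike in both groups could hardly remove that call. A difference in cell turnover or release in old dwarf mice could remain, and was not tested.

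Lymphocyte miRNAs were higher in old than in young normal serum. A rise in RNA of all white blood cells alike was argued against as the whole source, since the myeloid and platelet median was log2 0.41 (-0.21 to 0.73) against 1.60. Still, 7 of 9 members of that list were higher. Of these, miR-191-5p was called (log2 1.10), a call lost in 14 of 20 fits with 1 library left out. A smaller part shared by white blood cells stays open. With the erythroid list mean in the model the lymphocyte median was 1.65 (0.58 to 2.67) and 6 of 6 calls were kept. The erythroid list did not itself differ between these groups (median log2 -0.05, camera adjusted p 0.983). A model with its mean could therefore hardly remove the rise, and this fit decides nothing about red-cell RNA. Haemolysis as the index measures it cannot be told apart from the age difference: the index fell with age, and with it in the model the median was 1.14 (0.14 to 2.10), 1 of 6 calls was kept and the median standard error rose from 0.390 to 0.446. A lower red-cell share, which would raise all other miRNAs alike, also cannot be told apart by other lists, since the lymphocyte median exceeded theirs by 1.37 (0.22 to 2.34), an interval too wide to decide against 1.60. Lists did not move alike, with medians of log2 -3.16 for Dlk1-Dio3, -1.49 for muscle, 0.41 for myeloid and platelet and 0.56 for neural and endocrine miRNAs. That argues against such a share as the only source of all changes with age, while a part in the lymphocyte rise stays open. A change in lymphocyte number or release with age stays open and was not tested.

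The same libraries were split in 100 ways, the real split included. For old dwarf against old normal mice 1 split gave at least as many calls as the real one (95, highest other 69). For old against young normal mice 3 did (56, highest other 66). Both numbers lie under the planned limit of 5 splits, without adjustment over the comparisons. Since another split gave more calls than the real one in normal mice, chance is not excluded there. The limit was reached for old against young dwarf mice (6 splits, 2, highest other 44) and the difference of age effects (5 splits, 2, highest other 142), so chance stays open for these. For young dwarf against young normal mice all 100 splits gave at least as many calls because the real split gave 0 (highest other 22), so this count says nothing about chance. Splits with 22, 44 and 142 calls, against 0, 2 and 2, point to a structure of the samples that does not follow the groups. In old against young normal mice, the split with 66 calls, against 56, exchanged young normal replicate 1 and old normal replicate 4. Such structure may reach this comparison too.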

How the results depend on the processing

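The fits with a lymphocyte or an erythroid covariate and the one counting identical names once were chosen after the data were seen, and the other alternatives were planned. No miRNA or list past the threshold changed direction. Among miRNAs not past it, direction changed with the haemolysis index for miR-451a in old dwarf against old normal mice (log2 -0.0716) and for miR-16-5p (0.13), miR-23a-3p (-0.0884) and miR-122-5p (1.64) in old against young normal mice, with library totals for miR-23a-3p in old against young normal (-0.35) and miR-449a-5p (-0.33) and miR-342-3p (-0.26) in old against young dwarf mice, with both groups fitted alone for miR-23a-3p in normal mice (-0.11), and with upper-quartile factors (0.0474) or the replicate block (0.0447) for miR-150-5p in dwarf mice. Leave-one-out values ran from -1.26 to 0.71 for miR-122-5p in old against young normal mice, and in old against young dwarf mice from -0.14 to 0.28 for miR-449a-5p, -0.49 to 0.16 for miR-127-3p and -0.22 to 0.12 for miR-150-5p. Young dwarf against young normal calls numbered 6 with DESeq2 and 1 with no filter, the haemolysis index or the erythroid covariate, against 0. Old dwarf against old normal calls numbered 63 with both groups fitted alone and 0 with the haemolysis index or the lymphocyte covariate, against 95. Old against young normal calls numbered 106 with library totals, 117 with DESeq2, 128 with the erythroid covariate, 34 with both groups fitted alone, 1 with the haemolysis index and 0 with the lymphocyte covariate, against 56. The lymphocyte list mean itself set the old normal libraries apart (7.18 to 8.93 log2 CPM, against 6.27 to 6.96 in all others). A model with it could therefore hardly keep calls against old normal mice, and its counts say nothing about the processing. Old against young dwarf calls numbered 0 with library totals, the stricter filter, both groups fitted alone or the replicate block, 1 with summed precursor rows and 7 with the erythroid covariate, against 2. For the difference of age effects they numbered 1 with RLE factors, 20 with DESeq2, 13 with no filter, 39 with the erythroid covariate, and 0 with library totals, upper-quartile factors, the stricter filter, the haemolysis index, the replicate block, summed rows, robust dispersion or the lymphocyte covariate, against 2. The similarity of age effects was 0.477 as Spearman's rho, against 0.335. Of the values of named miRNAs, 1150 stayed on their side of the threshold under other settings, 130 lost and 33 gained a call, and 1940, 183 and 8 when 1 library was left out. For lists these were 952, 35 and 32, and 1451, 25 and 24. Leave-one-out ranges were 0 to 0, 51 to 143, 29 to 123, 0 to 2 and 0 to 3 calls in the same order, and for the haemolysis index 0.784 to 1.21 in old dwarf against old normal and -1.35 to -0.853 in old against young normal mice. The replicate block gave 92 calls for old dwarf against old normal and 38 for old against young normal mice. Replicate numbers did not pair libraries (mean r -0.0104 between libraries of 1 number, 3 of 20 libraries most similar to 1 of their own number). Beyond the lymphocyte covariate and the smaller number of samples in fits of both groups alone, the cause of these changes was not tested. Depth may limit low miRNAs, which was not tested, and of tested 2-fold changes 33.3% or fewer were recovered in simulated counts.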

Other observations

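The miRNAs in this paragraph, and the libraries named in the next, were chosen after their values were seen. Outside the fixed lists, miR-199a-3p, whose reads are shared with miR-199b-3p, stood at 208.2 ± 73.9 CPM in old normal mice against 1034 ± 802.5 in young normal and 900.6 CPM in old dwarf mice (log2 2.11 ± 0.57 in old dwarf against old normal, edgeR adjusted p 0.0121, and -2.31 ± 0.58 with age in normal mice, adjusted p 0.0125). miR-218-5p, encoded in an intron of the axon guidance gene Slit2 (chromosome 5, 48223942 to 48224051), stood at 1.92 CPM in old normal, 16.3 in young normal and 18.3 CPM in old dwarf mice (log2 3.21 ± 0.85, adjusted p 0.0113, and -3.05 with age in normal mice, adjusted p 0.019, which was 0.0571 without young normal replicate 5).

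Principal component 1 of log CPM held 65.3% of the variance. It followed the Dlk1-Dio3 list mean (r 0.991, with 39.6% of its squared loadings) and the muscle list mean (r 0.864, 4.81%), and went against the neural and endocrine (r -0.929), myeloid and platelet (-0.876), Sfmbt2 (-0.805) and erythroid (-0.767) list means. Old normal libraries lay at -18.9 to -11.9 on it, with young normal replicate 1 at -14.9 within that range. Young normal replicate 4 (-10.8), old dwarf replicates 3 (-8.36) and 2 (-7.95) and young dwarf replicate 1 (-6.55) came next, and the other libraries lay at 6.94 to 18.6. In the Dlk1-Dio3 list mean, young normal replicates 1 and 4 (1.66 and 1.85), young dwarf replicate 1 (2.62) and old dwarf replicates 2 and 3 (2.26 and 1.92) lay nearest the old normal libraries.

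The authors' deposited miRDeep2 report listed 536 hairpin candidates. Of these, 29 had a score of at least 10, and 3 of them with an rRNA or tRNA alert held 95.1% of the reads (80069 of 84233). That report counted 1124 of 1915 known mature miRNAs in the data.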
